A study of Mus musculus with 6 samples.

How the data were processed

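Total RNA of sort-purified CD4+CD8+ thymocytes from 3 Flvcr control and 3 Flvcr-deleted samples was labelled with biotin and hybridised to Illumina bead arrays, 1 array per sample. Groups and replicate numbers were taken from the sample titles. The deposited table of non-normalized values held probe intensities on a linear scale, with no scaling between arrays, and a detection p-value for each probe and array, per the file headers. Array medians of these intensities ran from 126.1 to 149.1. A second deposited table held log2 values, and the submitters' processing notes name lumi without a version. Set against the intensities, these log2 values equalled the log2 of the quantile-normalized intensities of the same arrays to within 5.00e-09, with no background correction, so their scale was settled and no centring was found. Their medians were 7.09 on each array. No chip, slide or scan date was given in the headers, and the genome build and probe positions were not given in the sources used here.

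Probe names came from the platform annotation, in which 35784 of 45281 probes had 1 gene symbol, 0 had several and 9497 had none. Symbols were updated through the RefSeq gene table of assembly GRCm38.p6, by gene identifier for 28620 probes, by accession for 2637, by current symbol for 2128 and by a unique synonym for 2343, while 56 kept the name in the annotation. That table was used only for names and for which genes neighbour each other.

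Intensities were background-corrected, quantile-normalized and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3, with an offset of 16 and the negative controls inferred from the detection p-values. Probes with a detection p under 0.05 on at least 3 arrays were kept, which left 15448 probes, 13445 of them with a gene. A gene was represented by its kept probe with the highest mean, and unnamed probes were tested but counted only among probes. Flvcr-deleted arrays were compared with control arrays with lmFit and eBayes with a variance trend, 2-sided, and p-values were adjusted by the Benjamini-Hochberg method over all kept probes, with a threshold of 0.05. Log2 fold changes are Flvcr-deleted minus control, on the background-corrected scale with the offset, which understates changes of dim probes. For a probe not detected on any array of a group, the fold is a bound that holds on this scale only. It sets the bright group's mean against, per array, the higher of the lowest detected signal and the probe's own.

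In total, 31 gene lists for heme and iron metabolism, stress, thymocyte stages, other cell types and sample quality were fixed before the data were examined, as were the tests of the comparisons in the report, the test of neighbours of Flvcr1, the rule for named genes and most alternatives. Lists with at least 5 kept genes were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry beside it, and adjusted over the 25 lists tested. Members were also adjusted over the list alone. Named were Flvcr1, then up to 12 genes per direction past an adjusted p of 0.05 whose groups did not overlap, then up to 4 passing members of each list or the 2 with the smallest p, and for other cell types and sample quality the 2 most abundant members. Further genes named and the unnamed probes were chosen after their values were seen. These genes were Hmox1, Rag1, Rag2, Cd4, Cd8b1, Cd8a, Eif2s3y, Iglv1, H2-Eb1, Jchain, Ms4a1, Nqo1, Srxn1, Hspa1a, Atf3 and a further kappa segment. Changed genes within 20 Mb of Flvcr1 were compared with all others by Fisher's exact test.

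Alternatives changed 1 choice at a time: background correction, normalization, the deposited log2 values, the probe filter (none, or a strict detection filter with p under 0.01 on all arrays of at least 1 group), the variance model, array weights, a replicate block, each array left out, the mean of a gene's probes, thresholds, the set test and the window. A chip block was not run, because no chip was given. Covariates for Xist and for globin, and counting Flvcr1 among its neighbours, were added after the data were seen.

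The procedure was tested on simulated arrays built from these arrays' background and spread, with no signal at probes that were not kept. Of 15461 simulated probes tested, 67 were changed 1.5-fold, 67 were changed 2-fold and 66 were changed 4-fold, and 22.4%, 62.7% and 97.0% of them were called, with 0 false calls and 0 wrong signs. Changed probes were drawn only from the brighter kept probes. The dimmest probes were given a fixed spread in place of their own, and large spreads were capped. These rates therefore do not describe dim probes. In a first version, background probes kept a small signal and more probes passed the filter than in the data, so that signal was removed. Simulated genes varied independently, so the correlation between real genes was not simulated. Of 200 random lists of 15 unchanged genes, 2% had a camera p under 0.05. Figures were drawn with matplotlib.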

Results

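Gene expression was measured on 6 Illumina bead arrays, each hybridised with total RNA of sort-purified CD4+CD8+ double-positive thymocytes from the thymus of mice on a C57BL/6 background. Double-positive thymocytes are the intermediate stage of T cell development that carries both coreceptors and undergoes positive selection. The arrays formed 2 groups of 3, Flvcr control (Flvcr+/+) and Flvcr-deleted (Flvcr-/-). Flvcr1 encodes a heme exporter of the plasma membrane, so the comparison asks how the transcripts of these cells differ when the exporter gene is deleted. Between 15307 and 15792 of 45281 probes were detected per array (33.8% to 34.9%), and 15448 probes, standing for 8808 genes, entered the tests. Correlations between arrays were 0.977 to 0.986 within groups and 0.978 to 0.984 between groups. The number of arrays limits the precision of all values below. Nothing states that the 3 samples of a group came from separate animals, so p-values measure the spread between these samples.

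The Flvcr1 transcript was lower on all 3 Flvcr-deleted arrays than on any control array. Its probe read 11.07 ± 0.18 (log2, SD, n = 3) in control and 10.16 ± 0.27 (SD, n = 3) in Flvcr-deleted cells, a log2 fold change of -0.91 (SE 0.157), or 1.88-fold lower. The adjusted p of limma was 0.0317. The probe's signal was well above background on all arrays, and whether its target lies inside the deleted part of the gene is not given in the sources used here, so the value is no strict check of the labels. The call was lost without the variance trend (adjusted p = 0.38) and without control replicate 1 (0.296), control replicate 2 (0.184), Flvcr-deleted replicate 1 (0.115) or Flvcr-deleted replicate 3 (0.233), while the log2 fold change stayed between -1.05 and -0.79 over all alternatives.

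Few genes differed between the genotypes, and most of those were lower in Flvcr-deleted cells. Of 8808 genes, 13 passed an adjusted p of 0.05, 2 higher and 11 lower, and all 13 had groups that did not overlap. At an unadjusted p under 0.05 there were 408 genes, 229 higher and 179 lower, where chance alone gives 440.4. Groups did not overlap for 845 genes (9.59%, against 10% by chance). Among probes, 26 of 15448 passed, 2 higher and 24 lower, and 13 of these 26 had no gene name. With scaling to a common median the split was 4 higher and 11 lower. The count fell to 1 gene without the variance trend and to 6 with the mean of a gene's probes, rose to 30 with array weights, and was 4 without control replicate 1, 2 without control replicate 2, 2 without Flvcr-deleted replicate 2 and 3 without Flvcr-deleted replicate 3.

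Among named genes, the largest difference was that of Igkc, a transcript of the immunoglobulin kappa locus. Igkc, the constant region of the kappa light chain, fell from 11.80 ± 0.35 in control to 8.44 ± 0.37 in Flvcr-deleted cells (log2, SD, n = 3 each), a log2 fold change of -3.36 (SE 0.202) or 10.3-fold lower (limma adjusted p = 5.09e-07). It was the only called gene that kept its call under every one of the 17 alternatives that gave it a value, with log2 fold changes of -3.54 to -2.99. The kappa variable segment Igkv6-23 and a second kappa variable segment (probe ILMN_1220577) were detected on all 3 control arrays and on 0 Flvcr-deleted arrays. They were at least 3.62-fold and at least 3.21-fold lower (adjusted p = 0.00925 for each), these bounds being set by the lowest signal among detected probes. They lost their calls under 2 and 3 of the 14 alternatives that gave them a value. Both passed the detection filter only through the control arrays, so leaving out any control array removed them from the test. Both bounds hold on the background-corrected scale: without background correction the log2 fold changes were -0.94 and -0.84, still past 0.05 (adjusted p = 0.0387 and 0.0205). The mu heavy chain gene Ighm stood at 13.21 ± 0.05 in control and 13.16 ± 0.10 in Flvcr-deleted cells and did not pass. Among the 13 unnamed probes that fell, ILMN_2704562 and ILMN_1247185 had the smallest adjusted p. ILMN_2704562 had a log2 fold change of -3.61 (12.2-fold lower, adjusted p = 5.03e-07). ILMN_1247185 was at least 4.60-fold lower on the background-corrected scale (adjusted p = 2.65e-05). Like most of the 13, it was detected on 3 control and 0 Flvcr-deleted arrays. Leaving out any control array therefore removed it from the test.

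The remaining lower genes had no common list. Smoc1, which encodes a secreted calcium-binding matrix protein, fell by 2.05 on the log2 scale (SE 0.354, adjusted p = 0.0317). Tmie, a transmembrane gene of the inner ear, fell by 1.51 (adjusted p = 0.0203; log2 fold change -1.07 without background correction). Xkrx, of the XK-related family, fell by 1.24 (adjusted p = 0.00899). Bambi-ps1, a pseudogene, fell by 1.14 (adjusted p = 0.0469), the relaxin-family hormone gene Insl5 by 0.92 (adjusted p = 0.0453), and the Integrator subunit gene Ints7, a neighbour of Flvcr1 on chromosome 1, by 0.85 (adjusted p = 0.0441). Gramd3 was 2.82-fold lower on the called probe (adjusted p = 0.0298; log2 fold change -0.75 without background correction), while its other kept probe, at a mean of 5.61 and so near background, read -0.05 and did not pass. The 2 higher genes were Cox6a2, a tissue-restricted subunit of cytochrome c oxidase, and the histone H2B gene H2bc11. Cox6a2 had a log2 fold change of 1.51 (2.86-fold, SE 0.247, adjusted p = 0.0215), and 1.02 without background correction. H2bc11 stood at 0.87 (1.82-fold, SE 0.158, adjusted p = 0.0453). Clustered histone genes have near-identical copies that a probe may not tell apart. Each of these genes lost its call under at least 4 of the 17 alternatives.

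**Figure D1:**
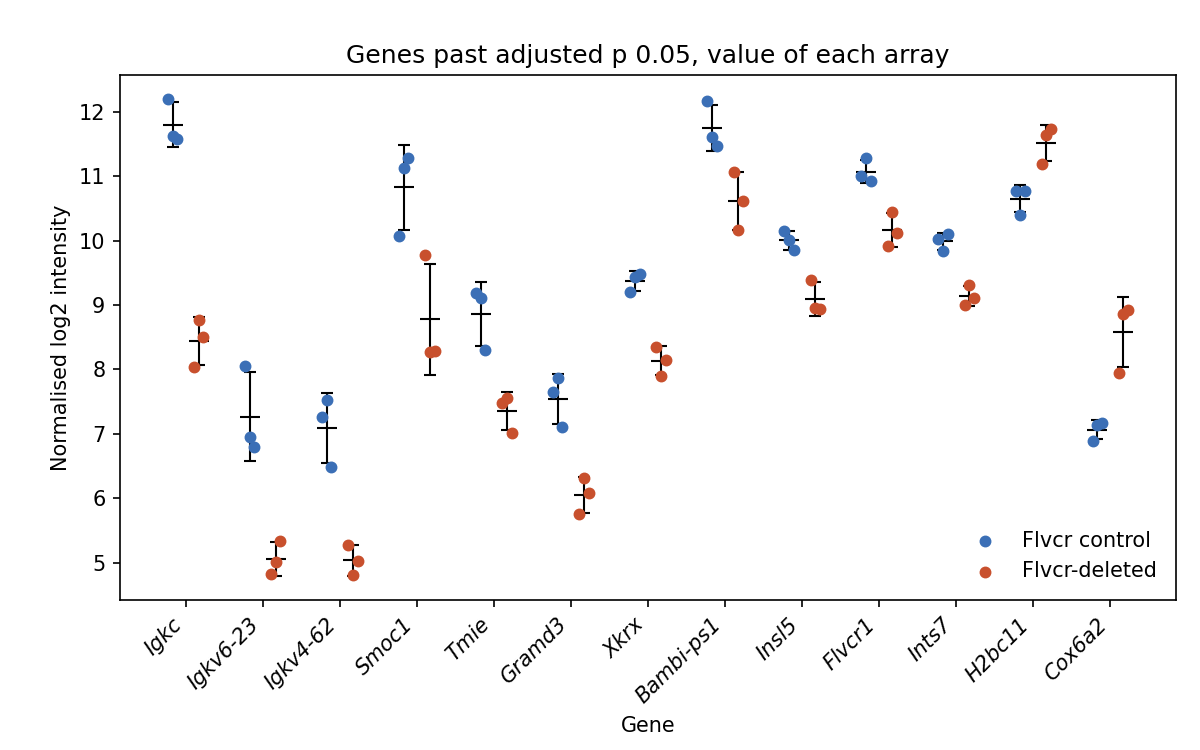
Normalised log2 intensity (vertical axis) of the 13 genes past an adjusted p of 0.05 (horizontal axis) on each of the 3 Flvcr control arrays (blue) and 3 Flvcr-deleted arrays (red), with the mean and SD in black. Igkc lies at 11.80 in control and 8.44 in Flvcr-deleted cells, and the groups do not overlap for any of the 13 genes.

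No list of heme or iron metabolism passed. Of 9 measured heme synthesis genes, 1 read higher and 8 lower, with a median log2 fold change of -0.05 (limma camera adjusted p = 0.683), and 0 passed either over all genes or adjusted over the list alone. Alad, an early enzyme of heme synthesis, stood at 0.33 (SE 0.186), and the transporter Abcb6 at -0.28 (SE 0.300). The 7 heme breakdown and transport genes had a median of 0.03 (adjusted p = 0.873), with Blvra, which reduces biliverdin, at 0.15 and Pgrmc2 at -0.13. Hmox1, the inducible heme oxygenase, was detected on at most 1 array and was not tested. The 12 iron handling genes had a median of 0.03 (adjusted p = 0.873), with 0.41 for Ireb2, the iron-responsive regulator, and -0.17 for the iron chaperone Pcbp2. None of these lists had a member past 0.05 adjusted over the list alone.

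None of the stress lists passed as a set over the members that were measured. Members detected on too few arrays were not tested, Nqo1, Srxn1, Hspa1a and Atf3 among them. Lack of detection may lie with the probe, since Cd8a was detected on 0 arrays of these CD8+ cells. The lists therefore leave such members open. Among 15 antioxidant genes the median was 0.00 and 0 passed over all genes. Adjusted over the list alone, 1 passed higher, the peroxidase gene Gpx1 (0.28), and 1 lower, the cystine transporter gene Slc7a11 (-0.85, and -1.09 with adjusted p = 0.0436 over all genes without Flvcr-deleted replicate 3). This list's median and mean lay just below 0 while its test pointed up (adjusted p = 0.89). Camera gave adjusted p = 0.323 for 12 p53 targets (median 0.08, Mdm2 0.37), 0.873 for 16 apoptosis regulators (median 0.02), 0.683 for 17 ATF4 and unfolded protein response genes (median 0.11), 0.73 for 8 heat shock genes (median 0.01) and 0.683 for 16 glycolysis genes (median -0.03, Pdk1 0.53 and P4ha1 -0.56). It gave 0.477 for 25 respiratory chain subunits (median 0.03), 0.0789 for 16 ribosomal protein genes (median 0.07, Rps24 0.26) and 0.683 for 14 interferon-stimulated genes (median -0.01). Adjusted over the list alone, 1 interferon-stimulated gene passed, Igtp, a GTPase (-0.43). For 9 circadian genes the adjusted p was 0.89, with a median of 0.05 but a mean of -0.02 and a test pointing down.

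Cholesterol synthesis and DNA replication genes passed as sets pointing up, by small amounts and only with the preset correlation. Of 14 cholesterol synthesis genes 12 read higher, with a median log2 fold change of 0.21 (camera adjusted p = 0.026, and adjusted p = 0.662 with an estimated correlation). Sqle, an oxygen-dependent enzyme of sterol synthesis, stood at 0.54 (SE 0.196) and Mvd, of the mevalonate pathway, at 0.49 (SE 0.225), and neither passed. Handling response genes leaned down in the same comparison (median -0.25). The set's call was lost without control replicate 1 (adjusted p = 0.204), control replicate 2 (0.108), Flvcr-deleted replicate 2 (0.149) or Flvcr-deleted replicate 3 (0.0733). Of 22 DNA replication genes 19 read higher, with a median of 0.14 (adjusted p = 0.026, and adjusted p = 0.925 with an estimated correlation), among them Prim1 at 0.70 and Tk1 at 0.45. The estimated correlation between the replication genes was 0.765. Their array means overlapped between groups, at 10.43, 9.91 and 10.57 on control replicates 1, 2 and 3. On Flvcr-deleted replicates 1, 2 and 3 the means were 10.22, 10.61 and 10.53. Without control replicate 2 this set pointed down (0.279), and it was lost without Flvcr-deleted replicate 2 (0.694) or replicate 3 (0.219), with the strict detection filter (0.0794), without the variance trend (0.0942) and with array weights (0.164). The 15 mitotic genes had a median of 0.13 and did not pass (adjusted p = 0.315), but they passed pointing down without control replicate 2 (0.0241) and pointing up without control replicate 3 (3.45e-05) or Flvcr-deleted replicate 1 (3.88e-05). The mean of the mitotic genes was 9.04 on control replicate 2 and 10.26 on control replicate 3, a range within 1 group that exceeded the difference between groups.

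The list of double-positive stage genes did not pass. The 14 measured members, which include Rag1, Rag2, Cd4 and Cd8b1 but not Cd8a, whose probes were detected on 0 arrays, had a median log2 fold change of 0.02 (adjusted p = 0.675). Their mean was -0.05 and the test pointed down, mostly through Slc7a11, the 1 member that passed adjusted over the list alone. In the list of 10 double-negative and beta-selection genes the median was 0.01 and the mean -0.03 (adjusted p = 0.446). Here 2 members passed lower adjusted over the list alone, the surface antigen gene Ly6d (-0.46, SE 0.0996) and the adhesion receptor gene Cd44 (-0.90, SE 0.235), while 0 passed over all genes. Positive selection genes (14 members, median 0.00, Cd69 -0.26), T cell receptor signalling genes (14 members, median 0.00) and the E-protein and RORgt network (13 members, median -0.10) gave adjusted p = 0.873, 0.89 and 0.312.

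Genes of mature single-positive cells and egress passed as a set pointing down, only with the preset correlation. Of 14 members 9 read lower, with a median log2 fold change of -0.24 (camera adjusted p = 0.00592, and adjusted p = 0.513 with an estimated correlation). With the 2 genes not detected on any Flvcr-deleted array at their bounds the median was -0.20, and camera was not run on these values. Both genes passed the detection filter only through the control arrays, so leaving out any control array removed them from the list. Lower members included Ccr7, a chemokine receptor also counted as a dendritic cell gene (-0.76, SE 0.289). Another was Nkg7, a cytotoxic granule gene detected on 0 Flvcr-deleted arrays. Nkg7 was at least 1.49-fold lower on the background-corrected scale, and the alternatives gave it log2 fold changes of -1.16 to -0.39. No member passed on its own. Handling response genes, with a median of -0.25 (-0.24 with Fosb at its bound), leaned down in the same comparison. The call was lost without control replicate 3 (adjusted p = 0.276) or Flvcr-deleted replicate 2 (0.0522), with the strict detection filter (0.113) and with array weights (0.0546). Dendritic cell genes also pointed down, 8 of 9 with a median of -0.13 (adjusted p = 0.026, and adjusted p = 0.662 with an estimated correlation). Cd74, the class II invariant chain, stood at -1.13 (SE 0.315) and alone passed adjusted over the list alone, while the abundant Cst3 and Bst2 stood at -0.07 and -0.24. This call was lost without control replicate 1 (adjusted p = 0.204), control replicate 3 (0.106), Flvcr-deleted replicate 1 (0.169) or Flvcr-deleted replicate 3 (0.156), and with the strict detection filter (0.064).

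Immediate early genes, which respond to cell handling, also passed as a set pointing down, with array means that overlapped between the groups. Of 12 members 10 read lower in Flvcr-deleted cells, with a median of -0.25 (adjusted p = 0.00592, and adjusted p = 0.695 with an estimated correlation). Fos stood at -1.12 (SE 0.433) and Jun at -0.81 (SE 0.403), whereas the abundant Nfkbia and Egr1 stood at -0.07 and 0.01. Fos passed over all genes with array weights (-1.92, limma adjusted p = 0.0496) and with a replicate block (-1.12, limma adjusted p = 0.0206). The mean of the list was 9.74, 9.15 and 8.82 on control replicates 1, 2 and 3 and 9.17, 8.84 and 8.58 on Flvcr-deleted replicates 1, 2 and 3. The call was lost without control replicate 1 (adjusted p = 0.504), Flvcr-deleted replicate 2 (0.0522) or Flvcr-deleted replicate 3 (0.147). Over the 25 lists tested, 5 passed with the preset correlation and 0 with an estimated correlation or by fry.

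In each list of other cells except the dendritic one, most markers were not measured, which does not show that the cells were absent. Some measured markers were bright in both groups, such as Prf1 (10.61 in control and 10.54 in Flvcr-deleted cells). The 5 erythroid genes had a median of -0.11 (adjusted p = 0.829), but the globin mean varied widely between arrays, at 11.20, 9.48 and 9.53 in control and 7.03, 11.53 and 11.57 in Flvcr-deleted replicates 1, 2 and 3. Lists with fewer than 5 measured members were not tested as sets. Of these, 3 macrophage genes had a median of 0.05 (Apoe 0.17, Slc11a1 0.03) and 4 B cell genes 0.08 (Cd79b 0.26). The 2 NK and gamma-delta genes had a median of -0.32 with Nkg7 at its bound. On the background-corrected scale Nkg7 was at least 1.49-fold lower and past 0.05 adjusted over the list alone, with Prf1 at -0.08. The 2 stromal genes had a median of 0.23 (Ccl25 0.52, Pecam1 -0.05). Of the granulocyte list, 0 members were kept. Xist was high on control replicates 1 and 2 (8.99 and 8.91) and Flvcr-deleted replicates 2 and 3 (9.39 and 9.18) and low on control replicate 3 (4.82) and Flvcr-deleted replicate 1 (4.66). The Y-linked gene Eif2s3y was high on the latter 2 arrays (10.12 and 9.99), so each group held 1 array with a male pattern.

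**Figure D2:**
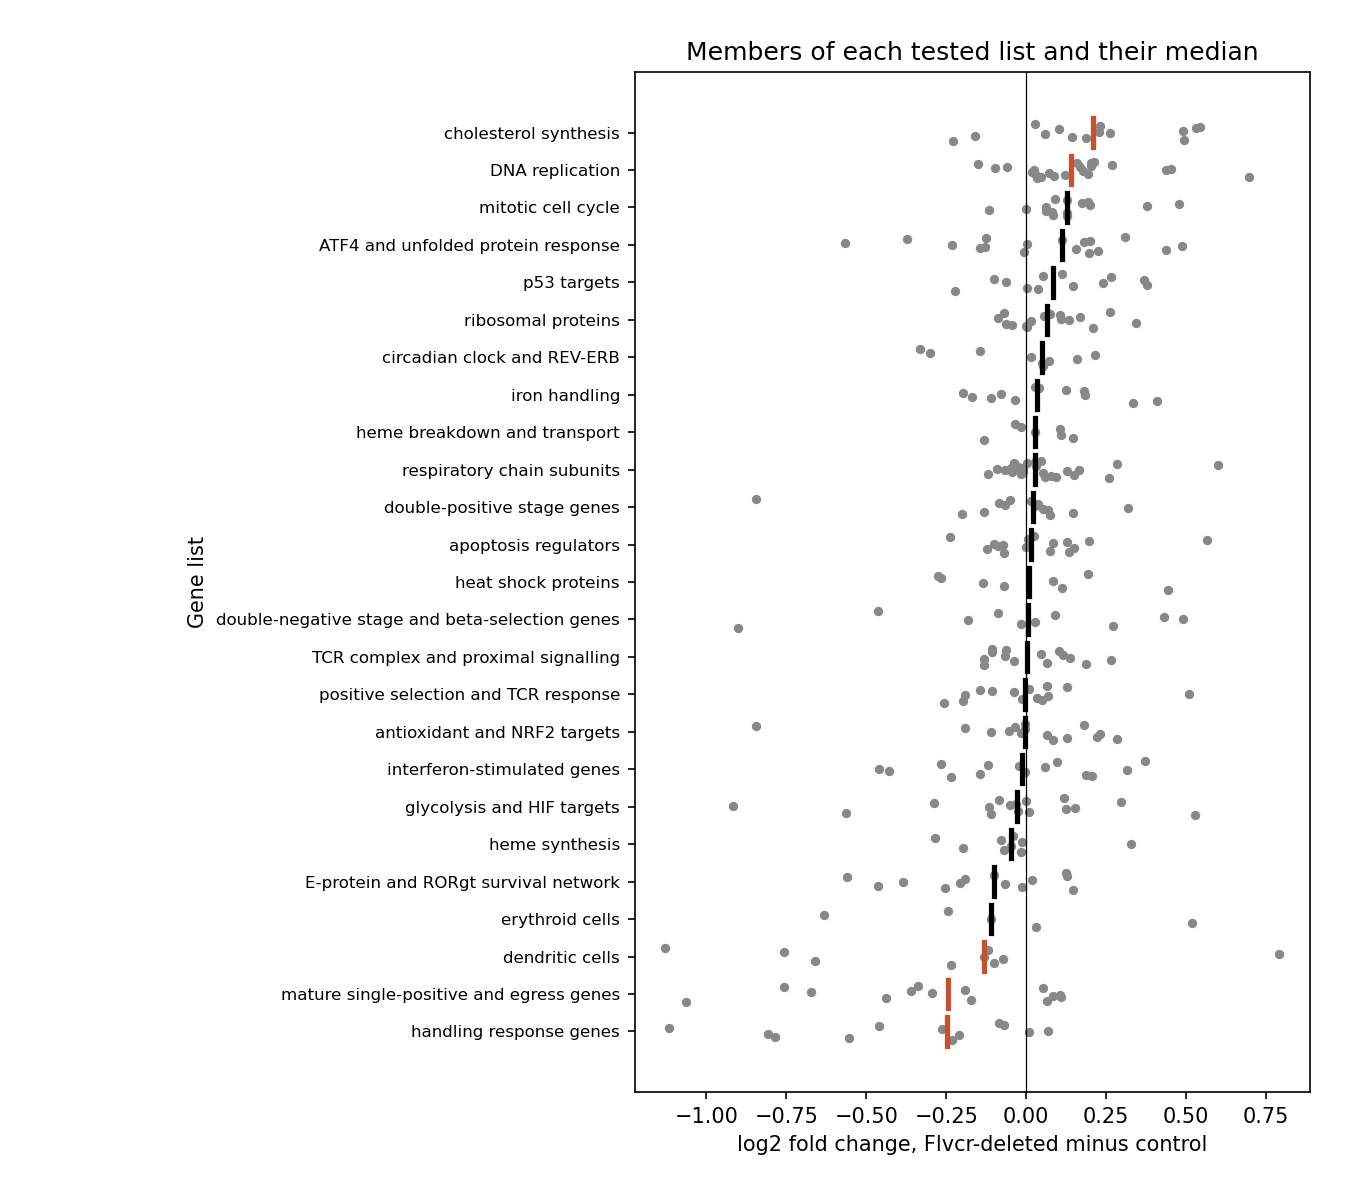
Log2 fold change (horizontal axis, Flvcr-deleted minus control) of each measured member (grey points) of the 25 tested gene lists (vertical axis), with the list's median as a bar, red where camera's adjusted p with the preset correlation was under 0.05. Medians run from -0.25 for handling response genes to 0.21 for cholesterol synthesis, and 5 bars are red.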

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

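The covariates for Xist and globin, and counting Flvcr1 among its neighbours, were chosen after the data were seen. The 13 genes became 1 without the variance trend, 30 with array weights, 6 with the mean of a gene's probes and 4 at an adjusted p under 0.01. Leaving out each array in turn gave 2 to 12 genes. The Flvcr1 difference kept its direction throughout, but without the trend (-0.91, adjusted p = 0.38) it no longer passed, and leaving out arrays gave -1.05 to -0.79, over a range of adjusted p from 0.0019 to 0.38 in all alternatives. The 5 gene lists became 2 with the strict detection filter, 3 with array weights, 0 with an estimated correlation and 0 by fry, and 1 to 5 without single arrays. Without Flvcr control replicate 2, the mitotic list (adjusted p = 0.0241) and the DNA replication list (0.279) pointed down, and over all single arrays left out their adjusted p ran from 3.45e-05 to 0.843 and from 1.63e-05 to 0.694. Neighbours of Flvcr1 passed (Fisher's exact p = 0.00902) only with Flvcr1 itself counted. Fewer samples enter the leave-one-out fits, and for the other settings the cause was not tested. Of the 12 called genes other than Flvcr1, 11 lost a call under some alternative, and of 64 named genes that were not called 2 gained one, Slc7a11 and Fos. Of the 25 tested lists, 19 kept their side of the threshold throughout. The deposited log2 values and the setting without background correction are the same values and gave 11 genes each, all among the 13. Nothing states that replicate numbers pair the samples. Deviations of same-numbered arrays correlated at -0.148, 0.0927 and 0.109, which is weak but cannot exclude pairing with so few arrays. With a replicate block 12 genes passed, of which 10 were among the 13. The chip block was not run because no chip was given. Median signal over background was 2.83 to 3.09 per array, and dim probes are limited by it.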

Other observations

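The tests of B-lineage cells, of processing for Igkc and of splits for histone genes were chosen only after the results were seen. Besides the kappa transcripts that passed, 2 light chain segments read lower on average in Flvcr-deleted cells but did not pass. The lambda segment Iglv1 had a log2 fold change of -1.96 (SE 0.985, adjusted p = 1). It read 8.50, 6.46 and 9.99 on control replicates 1, 2 and 3 and 4.80, 9.44 and 4.84 on Flvcr-deleted replicates 1, 2 and 3, so it was high on arrays of both genotypes. A further kappa variable segment (probe ILMN_1228607) had a log2 fold change of -0.87 (SE 0.514, adjusted p = 1). It read 4.93, 7.16 and 6.81 in control and 6.47, 5.01 and 4.82 in Flvcr-deleted replicates, with overlapping groups. The other kept probe of this segment (ILMN_2631259) had a log2 fold change of -0.23 (SE 0.395) and was highest on Flvcr-deleted replicate 1 (6.06).

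Histone genes, a family chosen by symbol after the data were seen, leaned up in Flvcr-deleted cells. Of 52 measured genes, 42 were positive, with a median log2 fold change of 0.33. All but H1f10 lie in the histone clusters, and without it 41 of 51 were positive, with a median of 0.31. The median of all 52 was 0.34 with scaling to a common median and 0.21 in the deposited log2 values. The camera p was 4.15e-15 with the preset correlation and 0.073 with an estimated correlation, and 1 gene, H2bc11, passed over all genes. Without Flvcr control replicate 2, whose histone mean was the lowest at 10.07, the median was 0.17, and without Flvcr control replicate 3 it was 0.50.

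For the histone genes, a larger share of dividing cells was tested by adding each array's mitotic mean as a covariate. The median then was 0.26, or 78.2% of its value, and 44 of 52 genes were positive, against 42 without the covariate. The bound fixed before that value was seen was 75%, which 78.2% met. A margin beyond its spread was required only afterwards. The margin of 0.0107 was smaller than its bootstrap SE of 0.0196, which resampled genes and not arrays. The covariate held mitotic genes only. The mean of the DNA replication genes was not used, so a larger share of cells replicating DNA was not tested. Dividing cells may therefore still account for part or all of the shift. Among 10 splits of the 6 arrays into 3 and 3, 2 gave a median as large, the real one included, and the highest other was 0.51. That other split set control replicates 1 and 2 and Flvcr-deleted replicate 1 against the rest. These 3 arrays had the lowest mitotic means, at 9.75, 9.04 and 9.30. The means were 10.26 on control replicate 3 and 10.19 and 9.97 on Flvcr-deleted replicates 2 and 3. The splits are too few for a share under 0.05. A difference of genotype stays open as well, untested against these.

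For the lower kappa transcripts, B-lineage cells present in the control sorts were weighed first, cells that sorting for CD4 and CD8 should remove. Over 16 markers (the B cell list and 4 class II genes) the median excess of signal in control arrays was 0.227% of the Igkc excess, with 4 markers not detected on any array, Jchain and Ms4a1 among them. This does not exclude B-lineage cells, because several markers lie near the floor, Ighm and Cd79b have high baselines in these cells, and 2 class II genes, Cd74 (-1.13) and H2-Eb1 (-0.66), were lower at an unadjusted p under 0.05, a condition added after the median was seen. Processing as the whole cause is argued against: Igkc passed at -2.99 in the deposited log2 values, which are quantile-normalized without background correction, and at -3.34 with scaling to a common median in place of quantile normalization. Contaminating plasma or B cells and kappa transcription in the thymocytes themselves may both remain as candidate explanations.

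Ints7 lies near Flvcr1 on chromosome 1, and flanking sequence of another strain carried with a targeted allele could lower a probe's signal. Within 20 Mb of Flvcr1, 1 of 98 genes had changed, Flvcr1 left out, against 11 of 8697 elsewhere, an odds ratio of 8.13 (95% interval 0.187 to 56.9, Fisher's exact p = 0.126). The odds ratio was 19.3 within 10 Mb, 4.87 within 50 Mb and 1.81 at an unadjusted p under 0.01, where 2 of 98 genes passed against 99 of 8697. The second of these 2 was Ptpn14, named after its value was seen. It was detected on 0 Flvcr-deleted arrays and so at least 1.61-fold lower on the background-corrected scale, and did not pass (adjusted p = 0.651). With so few genes the interval leaves the question open.

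Of the 10 splits of the 6 arrays, 1 gave as many changed genes, which was the real one with 13, and the highest other gave 2. The splits are too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 408 genes, while 3 other splits gave more, with 538, 863 and 1014.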
